A study of Mus musculus with 12 samples.

How the data were processed

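Pituitary RNA was measured by bulk RNA sequencing in 12 libraries from C57BL/6 mice. The labels give 4 groups of 3 libraries: mice with a floxed Gpr101 gene that carried a control virus or a cre virus, each given vehicle or the ligand AA14 for 1 week. Here these groups are called ctrl_vehicle, ctrl_AA14, cre_vehicle and cre_AA14, and the libraries are numbered as in their titles. The labels do not say which libraries came from separate mice, so the p-values measure the spread between these libraries.

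The authors deposited whole-number counts per gene for each library. Per the labels' protocols, RNA was isolated with TRIzol, libraries were made with a NEBNext Ultra RNA kit and sequenced as paired reads on a NovaSeq instrument, and reads were mapped with HISAT2 version 2.0.0. Per the submitters' processing notes, featureCounts 1.5.0-p3, DESeq 1.8.3 and the genome build GRCm38 were used. The annotation release, the strand setting and the handling of reads that fit several or overlapping genes are not given in the sources used here, so counts of overlapping genes and near-identical copies are uncertain. Each table held 55421 gene IDs, of which 55154 matched a gene symbol in a mouse gene name table. IDs without a symbol held at most 0.0135% of a library's counts. Coordinates are from a GENCODE annotation of GRCm38.

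Totals ranged from 48693682 to 73388221 counts per library. Among genes with a mean of at least 1 CPM (a gene's counts scaled to library size), the median standard error (SE, defined below) of a log2 fold change between 2 groups of 3 libraries was 0.26. Genes were kept with the filterByExpr function of edgeR 4.0.16, which left 22630 genes, and libraries were scaled with TMM factors. Quasi-likelihood F tests in edgeR were run on a model with 1 mean per group over all 12 libraries, with Benjamini-Hochberg adjustment at 0.05 and no fold minimum. The 7 comparisons were the AA14 effect in each genotype, the difference between these effects, the cre effect under each treatment, and the average of each effect. Each SE given here is the absolute log2 fold change divided by the square root of the F statistic. It is not a direct estimate, and for a gene with few counts it can be smaller than counting error. CPM values use the same scaling and are given as mean ± SD. The common biological coefficient of variation was 0.445.

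Gpr101 was compared between 6 cre and 6 control libraries with an exact two-sided permutation test of log2(CPM + 0.5). Of 41 gene lists, 40 were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, with adjustment over the lists within a comparison. The remaining list holds sex-linked genes and served only to check the libraries. Each list was tested again with an estimated correlation and with fry. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined.

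By that rule Gpr101 and 7 hormone genes are always reported. Up to 12 genes per direction were to be named in a comparison (6 for the cre effect under AA14) among those past the threshold with an ordinary symbol, a mean of at least 1 CPM and no overlap between the groups compared. Where fewer passed, genes of smallest unadjusted p filled the direction up to 5. The symbol, mean and overlap criteria were applied to these genes too, which the rule left open. Up to 4 members were taken from each list that passed its test. The text gives a part of the genes so chosen. Gm47308 lies outside the rule, as do the genes given only library by library, such as Malat1 and Rab11a, and they were named after their values were seen.

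Alternatives were other size factors (RLE, upper quartile, library sizes without the hormone genes), DESeq2 1.42.0, limma-voom with quality weights, other low-count filters, a fit of the groups compared only, a minimum log2 fold change of 1, the replicate number as a block, and each library left out. Settings added after seeing the data were a fit without the 3 libraries whose oligodendrocyte markers had a mean log2 level above 5, a GC trend term and GC-corrected offsets. The same edgeR steps were tested on simulated counts for the AA14 comparison in control mice, over 22630 genes. They recovered 11.9% of 67 genes changed 2-fold, 64.2% of 67 changed 4-fold and 87.9% of 66 changed 8-fold, with 5 calls among the unchanged genes. Simulated genes were drawn independently around a single mean each, and only genes of at least 1 CPM were changed. The simulation held no differences shared by libraries across genes, so it does not give the error rate of the real data. GC content was taken from the longest transcript of each gene and was known for 99.8% of the genes tested.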

Results

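Transcript counts were obtained from the pituitary of mice carrying a floxed Gpr101 gene, which encodes a G protein-coupled receptor. The mice carried a virus with cre recombinase, which cuts out floxed sequence, or a control virus, and received vehicle or AA14, which the study names as a ligand, for 1 week. The 4 groups held 3 libraries each. Totals ranged from 48693682 counts in cre_vehicle 1 to 73388221 in cre_vehicle 2, and the 7 hormone genes took between 17.6% and 30.8% of a library's counts.

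Gpr101 (ENSMUSG00000036357, chromosome X, 57496668 to 57503757) was low in every library and was not detectably lower after cre. Its level was 1.65, 1.22 and 16.1 CPM in ctrl_vehicle, 3.30, 2.20 and 6.60 CPM in ctrl_AA14, 2.43, 4.29 and 1.29 CPM in cre_vehicle, and 2.57, 2.43 and 0.901 CPM in cre_AA14. The mean was 2.32 CPM over the 6 cre libraries and 5.18 CPM over the 6 control libraries. The log2 difference of -0.64 had an exact two-sided permutation p of 0.303. The highest value, in ctrl_vehicle 3, came with 293 CPM of the hypothalamic hormone transcript Avp, against at most 24.6 CPM in the other libraries. Without that library the log2 difference was -0.23 (exact permutation p = 0.604). The annotated gene has 5410 bp of exon sequence with its coding part in 1 exon, and gene-level counts do not show whether a part of it was removed.

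**Figure D1:**
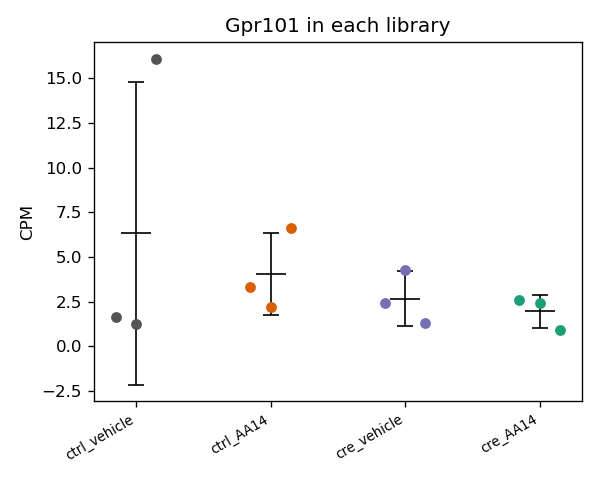
Gpr101 in CPM (vertical axis) in each of the 12 libraries, by group; points are libraries, and black marks are the mean ± SD of 3. The cre and control libraries overlapped, and the highest value, 16.1 CPM, was in ctrl_vehicle 3.

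The libraries differed in ways that the groups do not account for. The 3 ctrl_AA14 libraries, cre_vehicle 1 and cre_AA14 2 had between 1105 and 1560 CPM of Malat1, a nuclear-retained long noncoding RNA, while the other 7 had between 199 and 549 CPM. The same 5 libraries had 242 to 316 CPM of Ghrhr, the receptor for growth hormone-releasing hormone, against 84.0 to 160 CPM elsewhere. Their deviations from the mean fell with transcript GC content, with Spearman's rho across genes between -0.45 and -0.22, while rho lay between 0.01 and 0.42 in the other 7. This split coincides with treatment in control mice and takes 1 library of each group in cre mice. The list of oligodendrocyte markers had a mean log2 level above 5 in 3 libraries, ctrl_vehicle 3, ctrl_AA14 1 and cre_vehicle 2. The stress-induced transcripts Fos and Hspa1a reached 662 and 717 CPM in cre_AA14 1.

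**Figure D2:**
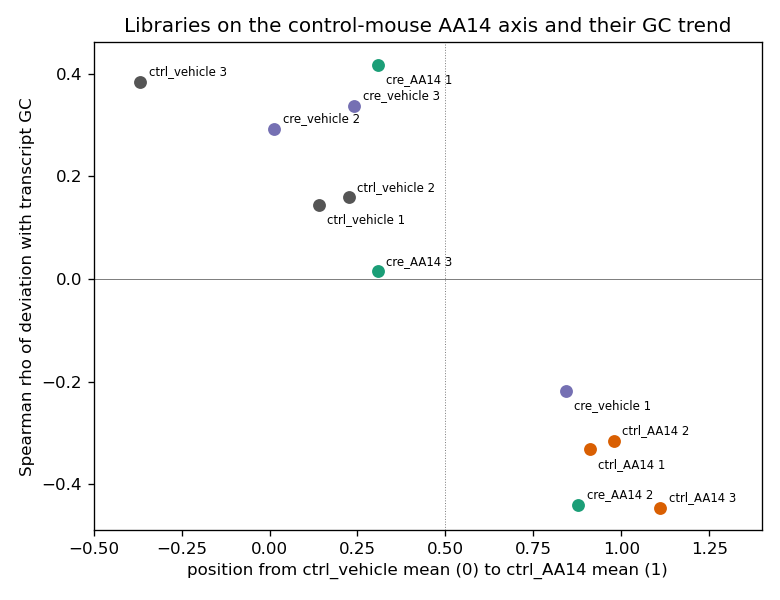
Position of each of the 12 libraries on the axis from the ctrl_vehicle mean (0) to the ctrl_AA14 mean (1) over log2 CPM (horizontal axis), against Spearman's rho of the library's deviation with transcript GC content (vertical axis); colours are groups. The library cre_vehicle 1 lay at 0.84 and cre_AA14 2 at 0.88, beside the ctrl_AA14 libraries.

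The first comparison asks how the pituitary responded to AA14 with the receptor gene intact. Growth hormone (Gh) was at 127900 ± 44000 CPM in ctrl_vehicle and 214500 ± 26610 CPM in ctrl_AA14 (n = 3 each), and thyrotropin beta (Tshb) at 243.0 ± 84.8 and 463 ± 76.6 CPM. Their log2 fold changes were 0.75 (SE 0.33, edgeR adjusted p = 0.195) and 0.93 (SE 0.37, adjusted p = 0.170), so neither passed the threshold. Tshb was at 386.1 to 539.3 CPM in the libraries rich in Malat1, with cre_vehicle 1 at 493.3 CPM, and at 146.5 to 360.5 CPM in the others. For Gh these ranges were 188700 to 241900 CPM and 90440 to 203900 CPM. In control mice AA14 and that library state coincide, so these values cannot tell them apart. Lhb, Fshb and Cga had positive log2 fold changes of 0.47 to 0.55, and Prl and Pomc had values of -0.40 and -0.52, with none past the threshold. Single libraries moved these values: Pomc was at -0.05 without ctrl_vehicle 1 and -0.82 without ctrl_vehicle 3, Prl at -0.64 without ctrl_vehicle 3 or ctrl_AA14 3 and -0.26 without ctrl_vehicle 2, and Fshb at 0.33 and Cga at 0.31 without ctrl_vehicle 3. With limma-voom and quality weights Tshb passed (adjusted p = 0.0400, the lowest of its alternatives, with 1.00 the highest).

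In the same comparison the protein genes of the mitochondrial genome rose as a list, with 13 of 13 members positive and a median log2 fold change of 0.39 (camera adjusted p = 9.47e-04, and adjusted p = 0.789 with an estimated correlation). Examples are mt-Co2, a cytochrome oxidase subunit, at 2660 ± 244 and 3807 ± 160.4 CPM, and mt-Atp6 at 437 ± 44.0 and 605 ± 26.8 CPM. Lists of extracellular matrix genes (16 of 17 negative, median -0.95, adjusted p = 0.00202), Gs pathway components (17 of 19 negative, median -0.64, adjusted p = 0.00202) and pituicyte markers (7 of 7 negative, median -1.51, adjusted p = 0.0420) fell, each with an adjusted p = 0.789 with an estimated correlation. Prkaca, a catalytic subunit of protein kinase A, was at 148 ± 32.4 and 50.6 ± 14.9 CPM, and the adenylyl cyclase Adcy5 at 142 ± 21.9 and 67.6 ± 8.73 CPM. Adjusted over the list alone, 7 Gs pathway genes, 3 pituicyte markers, 3 mitochondrial genes and 0 matrix genes passed, and adjusted over all genes none did. Mitochondrial and Gs pathway genes passed with any of the 6 libraries left out, while without ctrl_vehicle 3 the matrix (median -0.58) and pituicyte (median -0.64) lists did not, nor the pituicyte list without ctrl_AA14 2. The number of lists that passed was 7 without ctrl_vehicle 2. The falling lists came with Avp at 1.62 to 2.56 CPM in ctrl_AA14 and at 12.1 to 293 CPM in ctrl_vehicle. The mean log2 level of Gs pathway genes was 5.03 to 5.45 in the libraries rich in Malat1, with cre_vehicle 1 at 5.28, and 5.61 to 6.26 elsewhere. For matrix genes it was 3.81 to 3.93 and 4.20 to 5.37. All ctrl_AA14 libraries are rich in Malat1, so leaving out a single library cannot separate AA14 from that state. Of lists that did not pass by camera, adjusted over the list alone, the unfolded protein response had 6 genes higher and 2 lower, and the GH and IGF axis 5 lower. The cAMP-responsive genes had 8 positive and 9 negative members.

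Of single genes, 1 passed in edgeR, and 5386 of 22630 had an unadjusted p under 0.05, against 1132 expected by chance. The latter count was 3269 without ctrl_vehicle 3 and 3203 without ctrl_AA14 3. The called gene was Gm47308 (ENSMUSG00000104953, chromosome 9, 64726624 to 64726730), a predicted gene whose exon overlaps Rab11a, so that its count is uncertain. It was higher in 3 of 3 ctrl_AA14 libraries (log2 fold change 7.23, SE 0.34, edgeR adjusted p = 4.53e-06). It had 6 counts in all over ctrl_vehicle and 958 over ctrl_AA14, a ratio of 160.3 with an exact binomial 95% interval of 73.4 to 438 that covers counting error only. That interval is wider than the SE of 0.34 implies. The next genes did not pass the threshold. Krcc1 was at 51.0 ± 13.1 and 17.6 ± 1.24 CPM (log2 fold change -1.54, SE 0.19, edgeR adjusted p = 0.0592), the actin-nucleating Arp2/3 subunit Actr3 at 116 ± 8.31 and 55.5 ± 3.14 CPM, Dab2ip at 59.8 ± 10.5 and 22.0 ± 2.66 CPM, Ptprd at 44.0 ± 1.78 and 77.0 ± 6.37 CPM and Efemp1 at 109 ± 9.95 and 187 ± 9.85 CPM. Pcdhgb4 shares exons with its gene cluster and its count is uncertain.

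The number of calls in control mice differed between tools. DESeq2 called 2162 genes (508 higher, 1654 lower), limma-voom with quality weights 3409 (1153 and 2256), and an edgeR fit of the control mice alone 2266 (646 and 1620). With the GC trend of each library as a term, the genes at an unadjusted p under 0.05 numbered 511, and without the 3 libraries rich in oligodendrocyte markers 2380. The GC trend was negative only in the libraries rich in Malat1. In every comparison that term thus also takes up this library state, and in control mice the treatment.

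**Figure D3:**
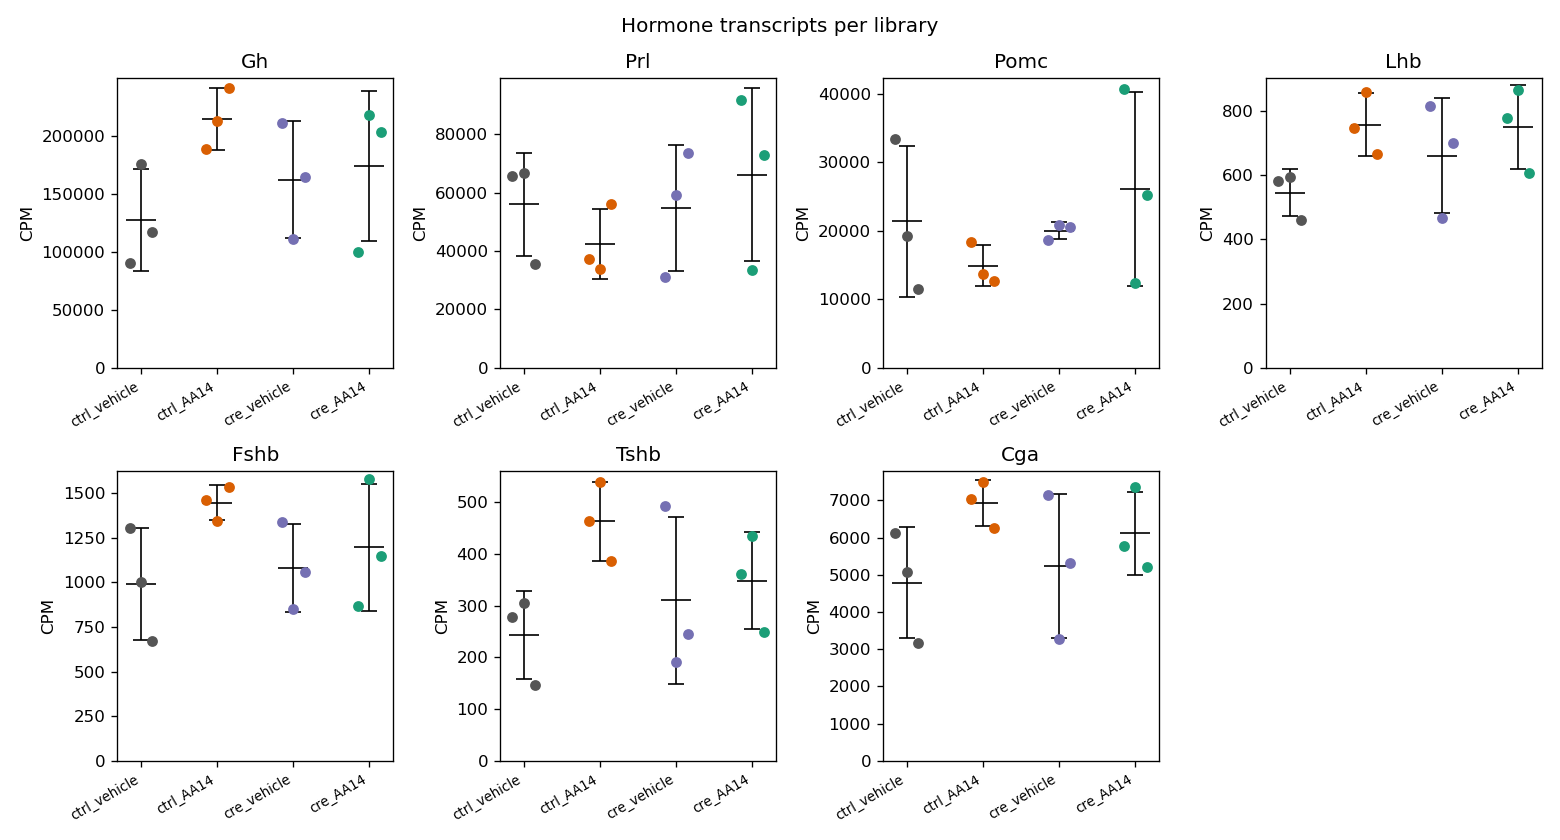
Hormone transcripts in CPM (vertical axes) in each of the 12 libraries, by group; points are libraries, and black marks are the mean ± SD of 3. Gh averaged 127900 CPM in ctrl_vehicle and 214500 CPM in ctrl_AA14, and no hormone gene passed the edgeR threshold in the comparisons between groups or in the difference of the AA14 effects.

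After cre, the response to AA14 was not detectable at single genes. Each cre group mixed both library states, with cre_vehicle 1 and cre_AA14 2 rich in Malat1. The absence of calls therefore does not show that a response was lost after cre. Gh was at 162300 ± 50400 CPM in cre_vehicle and 173800 ± 64680 CPM in cre_AA14, a log2 fold change of 0.10 (SE 0.32; -0.11 without cre_vehicle 2 and 0.37 without cre_AA14 1). All 7 hormone genes had log2 fold changes between 0.10 and 0.38, but each of the 7 was negative without at least 1 of the 6 libraries, such as Pomc at -0.10 and Prl at -0.05 without cre_AA14 1, Tshb at -0.09 and Cga at -0.03 without cre_vehicle 2, and Fshb at -0.11 without cre_AA14 2. In edgeR 0 genes passed. At an unadjusted p under 0.05 there were 519, fewer than the 1132 expected by chance (1462 without cre_vehicle 1, 821 with the GC trend as a term and 1213 in limma-voom). DESeq2 called 14 and limma-voom 0. Klhl20, among the named genes with lower values, was at 20.5 ± 1.31 and 10.7 ± 0.376 CPM (log2 fold change -0.94, SE 0.15, edgeR adjusted p = 1.00).

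Cytosolic ribosomal protein genes rose as a list in cre mice, with 39 of 39 positive and a median log2 fold change of 0.28 (camera adjusted p = 9.58e-20, and adjusted p = 0.710 with an estimated correlation). Lists of inflammation genes (13 of 13 positive, median 2.86, adjusted p = 1.81e-06) and of immediate-early and dissociation genes (16 of 17 positive, median 1.88, adjusted p = 0.00501) also rose, each with an adjusted p = 0.710 with an estimated correlation. Atf3, a stress-induced transcription factor, was at 174.5 CPM in cre_AA14 1 and at 2.14 and 1.13 CPM in the other 2 cre_AA14 libraries. The senescence (median 0.77) and interferon response (median 0.14) lists rose, and the erythroid (median -0.70), skeletal muscle (median -0.81) and mitochondrial (median -0.15) lists fell. With an estimated correlation none of these 5 held, with an adjusted p of 0.482 for skeletal muscle and 0.710 for the others. Adjusted over the list alone, 0 genes of the 8 lists passed. Without cre_AA14 1, the ribosomal list passed (median 0.13, camera adjusted p = 4.44e-05) and the other 7 did not. The medians without it were 0.10 for inflammation, -0.32 for immediate-early and dissociation, 0.08 for senescence, 0.12 for interferon response, -0.23 for erythroid, -0.50 for skeletal muscle and -0.01 for mitochondrial genes. By the direction of camera, the immediate-early and senescence lists turned. In all, 3 lists passed without cre_AA14 1. The senescence list shares Il6, Il1a, Cxcl1 and Ccl2 with the inflammation list, so the rises of these lists are not independent.

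The difference between the genotypes tests whether the response to AA14 depended on cre. Gm47308 was the 1 gene past the threshold in edgeR (log2 difference 7.04, SE 0.41, adjusted p = 4.36e-05), and 1591 genes had an unadjusted p under 0.05. That number was 4059 without cre_AA14 2, 2399 without cre_vehicle 2, 1050 without cre_AA14 3, 890 without cre_vehicle 1, 866 without ctrl_AA14 3 and 830 without cre_AA14 1. It was 617 with the GC trend of each library as a term and 3130 in limma-voom. The 617 lie below the 1132 expected by chance, but so did fits without that term, such as the 519 for AA14 in cre mice. A fall below 1132 therefore does not show that GC content was the cause. The change of Gm47308 lay in ctrl_vehicle, since the other 9 libraries had 4.15 to 6.62 CPM. The gene missed the threshold in limma-voom (adjusted p = 0.0507), the highest value of its alternatives, the lowest being 1.86e-20 in DESeq2. DESeq2 called 27 genes and limma-voom 0. For Gh the log2 difference was 0.65 (SE 0.46, edgeR adjusted p = 0.653) and for Tshb 0.77 (SE 0.52, adjusted p = 0.645), so a response that differed between genotypes was not shown for these hormones. The Gh difference was 0.36 without cre_AA14 1 and 0.41 without cre_vehicle 1, and that of Tshb 0.26 without cre_vehicle 1 and 0.50 without ctrl_vehicle 3. By camera 10 lists passed. Those of smallest p were mitochondrial genes, with a median difference of 0.56 (13 of 13 positive, camera adjusted p = 2.70e-07), and cytosolic ribosomal genes, with a median of -0.34 (38 of 39 negative, adjusted p = 1.01e-06). With an estimated correlation none of the 10 held, with adjusted p = 0.712 and 0.714 for these. Adjusted over the list alone, 1 lymphocyte gene passed and 0 of the other 9 lists. Of the 10 lists, 5 passed without ctrl_vehicle 3 and 6 without cre_vehicle 1 or cre_AA14 1. In all 16 lists passed without cre_AA14 3.

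Across genes, the AA14 fold changes of both genotypes had a Pearson's r of 0.17 and a Spearman's rho of 0.28 over 22630 genes, which are not independent replicates. Pearson's r was 0.37 over 16406 genes at a mean of at least 1 CPM and 0.41 over 10690 at 10 CPM. At an unadjusted p under 0.05, 15 genes were higher in both, against 21.9 expected for independent lists, and 36 were lower in both, against 38.9. Opposite directions were found for 14 genes higher in control and lower in cre mice, and for 6 genes the reverse. Most genes at that level in both genotypes thus shared a direction, but neither shared count was above the number expected for independent lists. The size of the overlap therefore gives no evidence of a common response. Over all genes Pearson's r was -0.09 without ctrl_vehicle 3, -0.07 without cre_vehicle 2, 0.008 without cre_AA14 2 and 0.32 without cre_vehicle 1.

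The cre virus alone, under vehicle, was compared next. Gm47308 was the 1 gene past the threshold in edgeR (log2 fold change 7.37, SE 0.34, adjusted p = 3.84e-06), with 452 genes at an unadjusted p under 0.05 (800 without ctrl_vehicle 2, 817 without cre_vehicle 2, 993 in limma-voom, 729 in DESeq2), 19 calls in DESeq2 and 2 in limma-voom. Krcc1 was at 51.0 ± 13.1 CPM in ctrl_vehicle and 17.5 ± 1.98 CPM in cre_vehicle (log2 fold change -1.54, SE 0.19, edgeR adjusted p = 0.0566), and it passed with RLE size factors (adjusted p = 0.0482, where all alternatives ranged from 1.22e-09 to 1.00). The same ctrl_vehicle libraries are the reference for AA14 in control mice, where ctrl_AA14 had a similar low level of Krcc1. The falls of Krcc1 in both comparisons are thus not separate effects of AA14 and cre. Scaf11 was at 52.7 ± 0.976 and 71.7 ± 1.84 CPM, and Cyp2f2 at 194 ± 9.95 and 279 ± 24.8 CPM, neither past the threshold. Hormone genes did not pass, with Gh at a log2 fold change of 0.34 (SE 0.32). That of Gh was 0.15 without ctrl_vehicle 1, 0.11 without cre_vehicle 1, 0.65 without ctrl_vehicle 2 and 0.55 without cre_vehicle 2.

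Of the lists, red cell genes (erythroid, 5 of 5 positive, median 1.25, camera adjusted p = 2.17e-05), lymphocyte markers (12 of 12 positive, median 0.38), mitochondrial genes (13 of 13 positive, median 0.22) and unfolded protein response genes (14 of 17 positive, median 0.11) rose under cre and vehicle. With an estimated correlation each had an adjusted p of 0.832. Macrophage markers (11 of 11 negative, median -0.32, adjusted p = 2.44e-04), nuclear respiratory chain genes (28 of 30 negative), ribosomal genes (34 of 39 negative) and interferon response genes (14 of 17 negative) fell. With an estimated correlation none of these held either, with adjusted p between 0.832 and 0.978. C1qa, a complement component made by macrophages, was at 44.7 ± 9.49 and 32.8 ± 5.54 CPM. Adjusted over the list alone, 1 lymphocyte gene passed and 0 of the other 7 lists. The erythroid list passed with any of the 6 libraries left out, and the other 7 each failed without at least 1 of them. Without cre_vehicle 1, 4 of the 8 lists passed. The camera direction turned for respiratory chain genes without ctrl_vehicle 3 and for ribosomal genes without ctrl_vehicle 1.

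Under AA14, cre and control libraries differed at 0 genes in edgeR, with 1927 at an unadjusted p under 0.05, 34 calls in DESeq2 and 0 in limma-voom. The 1927 became 4440 without cre_AA14 2, 1279 without ctrl_AA14 1, 1093 without cre_AA14 3, 724 without ctrl_AA14 3 and 619 without cre_AA14 1, and 556 with the GC trend as a term and 5893 in limma-voom. Gh was at 214500 ± 26610 CPM in ctrl_AA14 and 173800 ± 64680 CPM in cre_AA14 (log2 fold change -0.30, SE 0.32). In cre_AA14 1 it was at 99590 CPM and in the other 2 cre_AA14 libraries at 218000 and 203900 CPM, and without cre_AA14 1 the log2 fold change was -0.02 (SE 0.29; -0.49 without cre_AA14 2). Ptprd was at 77.0 ± 6.37 and 41.3 ± 3.17 CPM and Actr3 at 55.5 ± 3.14 and 109 ± 23.7 CPM, with an edgeR adjusted p of 0.582 for each. Both genes were also named for AA14 in control mice, which uses the same ctrl_AA14 libraries, so these differences are not independent of those. By camera 11 lists passed, 8 of them higher in cre_AA14, among them ribosomal genes (38 of 39 positive, median 0.23), extracellular matrix (15 of 17 positive, median 0.62), secretory granule genes (16 of 22 positive, median 0.32) and Gs pathway components (16 of 19 positive, median 0.36). None of the 11 held with an estimated correlation (adjusted p = 0.734 to 0.778). These lists came with Avp at 24.6, 1.67 and 16.2 CPM in cre_AA14 1, 2 and 3 and at 1.62 to 2.56 CPM in ctrl_AA14, and with a mean log2 level of pituicyte markers of 3.81, 2.72 and 3.85 against 2.70 to 3.33. Mitochondrial genes (13 of 13 negative, median -0.33) and cell cycle genes (17 of 18 negative, median -0.46) fell. Without cre_AA14 1 the ribosomal, matrix, mitochondrial and cell cycle lists passed and the other 7 did not. Adjusted over the list alone, 2 inflammation genes passed and 0 of the other 10 lists, and Atf3 stood at 174.5 CPM in cre_AA14 1.

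Averaged over genotypes, the AA14 effect had Gm47308 as its 1 call in edgeR, with 3929 genes at an unadjusted p under 0.05, 87 calls in DESeq2 and 2 in limma-voom. The 3929 became 6723 without cre_vehicle 1, 2488 without cre_AA14 2, 2475 without ctrl_AA14 3, 2449 without ctrl_vehicle 3 and 1934 without cre_vehicle 2, and 716 with the GC trend as a term, 862 without the 3 libraries rich in oligodendrocyte markers and 6107 in limma-voom. Averaged over treatments, the cre effect likewise had Gm47308 as its 1 call, with 443 genes at an unadjusted p under 0.05 (1632 without cre_vehicle 1, 1633 without cre_AA14 2, 4021 in limma-voom, 682 in DESeq2), 12 calls in DESeq2 and 2 in limma-voom. Gene lists past the camera threshold numbered 5 and 8, and 0 with an estimated correlation (adjusted p = 0.883 and 0.822). For the averaged AA14 effect, ribosomal, inflammation and unfolded protein response genes rose, and Gs pathway and matrix genes fell. Avp was at most at 2.56 CPM in 4 of the 6 AA14 libraries and 1 of the 6 vehicle libraries. Without cre_AA14 1, Gs pathway and matrix genes passed and the other 3 lists did not, with medians of 0.04 for ribosomal, 0.02 for inflammation and 0.28 for unfolded protein response genes. Without ctrl_vehicle 3, Gs pathway and inflammation genes passed and the other 3 did not. Without the 3 libraries rich in oligodendrocyte markers 0 lists passed for the averaged AA14 effect, and without ctrl_vehicle 1 the number was 12. For the averaged cre effect, 16 of 17 cAMP-responsive genes were positive, with a median log2 fold change of 0.32 (camera adjusted p = 0.0431). Without cre_AA14 1 that median was -0.08 (camera adjusted p = 0.947), and 1 of the 8 lists for this effect passed, as was so without cre_vehicle 3.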

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

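The tests of the ligand position, of overlapping genes and of neuron markers were chosen after the values were seen, as was the choice of GC-corrected offsets as a setting, whose result had not been seen.

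By the test of the difference between genotypes, the AA14 effect differed for Gm47308 (log2 difference 7.04) and, by camera with a preset correlation, for 10 gene lists. The median log2 differences were 0.56 for mitochondrially encoded genes, -0.34 for cytosolic ribosome, 1.72 for erythroid, -0.93 for extracellular matrix, 0.76 for lymphocyte, -0.52 for macrophage, -0.38 for Gs pathway components, 0.46 for cell cycle, -0.36 for secretory granule and -1.51 for pituicyte genes. None of the lists held with an estimated correlation (adjusted p = 0.712 to 0.742).

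The first pattern is the 5386 genes at an unadjusted p under 0.05 for AA14 in control mice. With GC-corrected offsets 5066 genes were at that level, against a bound of 1697 set for a GC bias as the whole cause, so a smooth GC trend alone does not account for the count. The trend as a model term gave 511, but rho was 0.14 to 0.38 in ctrl_vehicle and -0.45 to -0.31 in ctrl_AA14, so that term and the treatment are confounded. On an axis from the ctrl_vehicle mean at 0 to the ctrl_AA14 mean at 1, the library labelled cre_vehicle 1 lay at 0.84, cre_AA14 2 at 0.88 and the other 4 cre libraries between 0.01 and 0.31. A response to AA14 and a state of the libraries unrelated to it may each give this pattern and cannot be told apart, because 1 vehicle library is too few to decide, all 3 ctrl_AA14 libraries share the state, and an exchange of the labels of cre_vehicle 1 and a cre_AA14 library stays open, since the fits with cre_vehicle 1 exchanged for cre_AA14 1 or 3 gave 4635 and 3660 genes at that level in cre mice but either cause would raise them.

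The second pattern is Gm47308, the 1 gene at least 4-fold apart between ctrl_vehicle and all 9 other libraries. If the ctrl_vehicle libraries had been counted or prepared differently at many genes, more genes would be so far apart. As many were found for 17 of the 220 sets of 3 libraries, ctrl_vehicle among them, and 29 genes for the set rich in oligodendrocyte markers. This argues against a 4-fold difference of ctrl_vehicle alone at many genes. Resting on 1 gene, the test cannot decide on a difference at a few genes or on smaller ones. A difference shared with other libraries stays open, since Gm28048 was at most 0.0181 CPM in ctrl_vehicle, cre_vehicle 1 and cre_AA14 2 and at least 44.6 CPM in the other 7, and Skida1 at most 0.241 CPM in ctrl_vehicle and cre_vehicle 2 and at least 3.72 CPM in the other 8. The exon of Gm47308 overlaps Rab11a, itself at 108 to 118 CPM in ctrl_vehicle and 76.1 to 107 CPM elsewhere, so 100% of this pattern, 1 gene, overlaps another gene, but with a single gene that test is void and assignment of Rab11a reads may be involved.

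The third pattern is Gpr101 at 16.1 CPM in ctrl_vehicle 3. If brain tissue in the sample were the source, neuron markers would be highest there too, and 5 of 6 were, among them Gad1 at 62.9 CPM against a median of 0.225 CPM elsewhere and Camk2a at 147 against 20.1 CPM. The exception was Slc17a7, at 19.2 CPM against 19.8 CPM in cre_AA14 1, and 4 of the 6 had medians above 10 CPM elsewhere, which may come from the gland or from brain tissue there too. Brain tissue may therefore be a source of the Gpr101 reads there, as a hypothesis. The study's text names flow cytometry but no gate that would remove brain cells, and for Gpr101 in this library no biological explanation was tested.

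Other splits of the same libraries were counted for each number of calls. For AA14 in control mice, the real split gave 1 call and the highest of the others 0, and 1 of 10 splits gave as many. The values were 0 against 1 for AA14 in cre mice (10 of 10 splits), 1 against 1 for cre under vehicle (2 of 10) and 0 against 2 for cre under AA14 (10 of 10). A design with 10 splits cannot give a share under 0.05. At an unadjusted p under 0.05, AA14 in control mice gave 5386 genes and the highest of the other splits 1137. AA14 in cre mice gave 519 and the highest other split 4635, which exchanges cre_vehicle 1 and cre_AA14 1 and points to a structure of the libraries. For the averaged AA14 effect 10 of 100 drawn splits gave at least the 1 real call and the highest gave 4361. For the difference between genotypes 9 of 100 did and the highest gave 3418, and for the averaged cre effect 38 of 100 did and the highest gave 3. Chance is not excluded for these 3. The split with 4361 calls exchanges cre_vehicle 1 and cre_AA14 3 and puts all 5 libraries rich in Malat1 on one side, with 1 other, and the split with 3418 put cre_vehicle 1 and cre_AA14 2 together, which points to the same structure.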

How the results depend on the processing

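The fits without libraries rich in brain transcripts, with a GC term and with GC-corrected offsets were chosen after seeing the data, as was leaving out cre_vehicle 1 for AA14 in control mice. Numbers of genes past the threshold are 1, 0, 1, 1, 0, 1 and 1 for AA14 in control mice, AA14 in cre mice, their difference, cre under vehicle, cre under AA14, averaged AA14 and averaged cre. In that order DESeq2 gave 2162, 14, 27, 19, 34, 87 and 12. With limma-voom they were 3409 for AA14 in control mice, 0 for the difference and 2 each for cre under vehicle and both averages. A fit of the groups compared only gave 2266 for AA14 in control mice and 1 for cre under AA14. The count was 2 for AA14 in control mice with no filter and with GC-corrected offsets, for cre under vehicle with RLE factors and with GC-corrected offsets, and for averaged cre with upper-quartile factors and the stricter filter. Without the 3 libraries rich in brain transcripts it was 2 for AA14 in control mice, 1 for AA14 in cre mice, and 3 for the difference, cre under vehicle and averaged cre. The cause of these changes was not tested.

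Leaving out 1 library gave 1 to 5 genes for AA14 in control mice (5 without ctrl_vehicle 1 or cre_vehicle 1, 3 without ctrl_vehicle 3), 0 to 2 for AA14 in cre mice (2 without cre_AA14 1, 1 without cre_vehicle 2), 1 to 3 for the difference and for cre under vehicle (3 without ctrl_vehicle 1, ctrl_vehicle 3 or cre_vehicle 2), 0 to 1 for cre under AA14 (1 without cre_AA14 1), 1 to 4 for averaged AA14 (4 without ctrl_vehicle 1) and 1 to 3 for averaged cre (3 without cre_vehicle 2).

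Gene lists past the threshold numbered 4, 8, 10, 8, 11, 5 and 8 in the same order, and 0 in each with an estimated correlation or fry. The replicate block gave 8 for AA14 in control mice. Without the brain-rich libraries there were 2 for AA14 in control mice, 4 for cre under vehicle and 0 for averaged AA14. Leaving out 1 library gave 2 to 7, 3 to 11, 5 to 16, 5 to 8, 4 to 14, 2 to 12 and 1 to 14 lists. The r of both AA14 effects was 0.41 at a mean of at least 10 CPM, -0.075 without the brain-rich libraries, and -0.093 to 0.32 with 1 library left out (lowest without ctrl_vehicle 3, 0.32 without cre_vehicle 1).

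Replicate numbers did not pair the libraries: 13 of 18 same-numbered pairs had a correlation of deviations of at most 0.1. With the replicate block the counts of calls were 1 for AA14 in control mice and the same as without it in the other comparisons, and Gpr101 kept a log2 difference of -0.64 (exact permutation p = 0.324). Genes at an unadjusted p under 0.05 became 1004 for the difference and 1283 for cre under AA14 with the block. They became 321, 254 and 282 for AA14 in cre mice, cre under vehicle and averaged cre with the stricter filter, 719 and 914 for the last 2 with no filter, and 284 and 230 for the first 2 in a fit of the groups compared only. Of 4918 values of named genes under other settings, 4736 kept direction and side of the threshold, 109 passed it, 1 no longer did (Gm47308 in the difference, limma-voom), and 72 uncalled values changed sign without passing in either fit. In the main fit only Gm47308 was past the threshold, so most of these values are uncalled genes that stayed uncalled. Keeping the side of the threshold therefore says little about whether the named changes hold. Depth limits the ratio of Gm47308 between ctrl_AA14 and ctrl_vehicle, where it had 6 counts, to an interval of 73.4 to 438.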

Other observations

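The genes in this part were chosen after their values were seen, and none was tested. Immunoglobulin transcripts of plasma cells were highest in 4 libraries, all of them rich in Malat1, and low in ctrl_AA14 3, the remaining library of that state. Igha was at 26.8 and 26.2 CPM in ctrl_AA14 1 and 2, 32.3 CPM in cre_vehicle 1 and 10.1 CPM in cre_AA14 2, and at most 0.957 CPM in the other 8. Jchain, which joins secreted immunoglobulin units, was at 11.1, 11.7, 9.38 and 3.30 CPM in the same 4 libraries and at most 0.812 CPM elsewhere.

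Avp and Oxt, transcripts of the neurons that end in the posterior lobe, were low in the 5 libraries rich in Malat1. Avp was at 1.62 to 2.56 CPM there and at 12.1 to 293 CPM in the other 7, and Oxt at 4.62 to 8.18 against 14.5 to 105.3 CPM. The overlapping genes B3gnt2 and Gm28048 moved in opposite directions between libraries. B3gnt2 was at 45.4 to 57.8 CPM in ctrl_vehicle and 4.62 to 12.1 CPM in ctrl_AA14, and Gm28048 at most 0.0142 CPM and at 44.6 to 54.9 CPM, which coincides with treatment in control mice. B3gnt2 was also at 62.4 CPM in cre_vehicle 1 and 62.2 CPM in cre_AA14 2, where Gm28048 was at 0 and 0.0181 CPM. In the other 4 cre libraries B3gnt2 was at 2.19 to 4.24 CPM and Gm28048 at 48.8 to 59.8 CPM. As the genes overlap, the level of either alone is uncertain. All 12 libraries had male-type transcripts, with Ddx3y between 48.4 and 109 CPM and Xist at most 0.568 CPM.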
